A study of Bos taurus with 24 samples.

How the data were processed

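RNA of endometrial tissue from 12 Holstein Friesian cows, 6 control and 6 with subclinical endometritis, was hybridised to 24 Agilent bovine arrays of 2 colours. Each cow gave 1 caruncular and 1 intercaruncular array. The sample was in the red channel (Cy5) and a pool of equal amounts of all samples in the green channel (Cy3), per the labels, and no array had the dyes exchanged. The cow was the replicate throughout. Control and endometritis cows that share a replicate number are different animals, while the caruncular and intercaruncular arrays of a group with the same number belong to 1 cow per the labels.

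Spot and background intensity values are median pixel brightness in each channel, deposited as Agilent Feature Extraction 10.7.3.1 wrote them with no normalization. Processed intensity values were background-subtracted, spatially detrended and dye-normalized by the same software per the file headers. The log10 values are ratios of processed red over processed green per the file headers, and they were used only to check the matrix. The log2 values of the series matrix were processed by the authors, whose steps were not stated. In every column they had the opposite sign of the array's own ratio (r from -0.999 to -0.986, slope from -3.33 to -3.32 per log10 unit), so their sign was turned, and each of the 24 columns matched its own array best. The other columns hold flags of 0 or 1 that Feature Extraction set, per the file headers. Each array had 43803 spots that were not controls, with 43653 distinct probes, and 23509 probes could be given the symbol of 1 of 11068 genes through their RefSeq accession. Genes without a symbol were counted but not named. PGR, MKI67, FOXA2 and CSF3R could not be followed by name.

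Ratios were computed in R 4.3.3 with limma 3.58.1: normexp background correction with an offset of 50, loess within each array with control spots at weight 0, and no scaling between arrays. The plan had assumed mean spot signals, and medians were used in their place because the spot columns hold medians. Spots marked as outliers, 10 to 855 per array, were set to missing, none was saturated, and replicate spots of a probe were averaged. A probe was tested where its red signal was well above background on at least 6 arrays, and the probe with the highest mean signal stood for its gene, which left 22511 genes, 9949 of them with a symbol. Well above background were 74.7% to 82.3% of probes per array. Across arrays the median SD of a bright probe was 0.35 in the red and 0.13 in the green channel on the log2 scale. The 12 cows limit the precision: the median standard error of a gene was 0.12 on the log2 scale for endometritis with both tissues averaged, 0.13 and 0.14 in caruncular and intercaruncular tissue, 0.069 between the tissues and 0.14 for the interaction.

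Comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Endometritis was compared with control on the mean of each cow's arrays, in each tissue alone, and as the difference of the tissue effects (interaction). The tissues were compared with the cow as a block, and progesterone entered as log2 of ng/ml on animal means with the disease group as a covariate. All used limma's moderated fit, with p adjusted by Benjamini-Hochberg over all genes and a threshold of 0.05. PMN percentages were related to neutrophil markers by Pearson and Spearman correlation with exact permutation p in the 6 endometritis cows. Figures and tables were drawn with Python 3.11.15 and matplotlib 3.10.9.

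The 25 gene lists covered neutrophil, macrophage, T and NK, B and plasma cell, cytokine, antimicrobial, pattern recognition, complement, interferon-stimulated, antigen presentation, extracellular matrix, protease, epithelium, uterine gland, ciliated cell, stromal fibroblast, endothelial, smooth muscle, cell cycle, steroid receptor and progesterone-responsive, prostaglandin, immediate early and heat shock, erythrocyte, ribosomal protein and oxidative phosphorylation genes, with 9 to 40 members measured. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 25 lists. Members were also adjusted over the list alone. A list is called here when camera with the preset correlation passed.

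Genes were named by rule. Between the tissues these were the 10 largest differences per direction among genes past the threshold with the same sign in at least 10 of 12 cows. The same rule with 5 of 6 endometritis cows held for the disease comparisons, with 10 per direction for both tissues averaged, 6 for each tissue and 5 for the interaction, and for progesterone 5 per direction were taken. Where fewer than 5 genes passed, the 5 with the smallest p are given with their values. Of each list up to 4 members with the smallest p could be named, and ESR1 and OXTR were always given. Some genes that the rule would name are not reported here.

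The procedure was tested on simulated data. Of 100 genes shifted by 2-fold it recovered 78 with both tissues averaged, 71 in caruncular, 79 in intercaruncular, 94 between the tissues and 70 in the interaction, with 6 to 20 unchanged genes called, and of 100 shifted by 4-fold it recovered 90 to 99. A shift of 0.50 in the T and NK list was called, with 0 of the 24 other lists. Genes were simulated independently of each other, so this does not test list calls where genes are correlated. In caruncular tissue, other splits of the real cows called a median of 9 lists and up to 20. For pairing, cows of the 2 disease groups with the same number were checked and correlated at r from -0.141 to 0.287 in caruncular and from -0.366 to 0.605 in intercaruncular arrays, so they were not paired.

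Alternatives were the processed signals, the series matrix, no background subtraction, quantile normalization of average signal, scaling between arrays and a missing or stricter filter. Further ones were the mean of probes, every probe, a trended robust fit, array weights, the slide as a fixed or random block and the 4 slides with both groups. The replicate number as a block, progesterone as a covariate, only cows under 1 ng/ml and each cow left out were also run. Between the tissues, each disease group alone was fitted too. After the fits were seen, the match of each cow's arrays, fits without the 3 cows whose arrays did not match and the relation to the bacteriology score were added. Caruncular arrays lay at other positions of each slide than intercaruncular arrays, and slides 5 and 6 held 1 disease group each.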

Results

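Endometrium of 12 Holstein Friesian cows was profiled after calving on 24 bovine expression arrays. Control animals (n = 6) had 0% polymorphonuclear neutrophils (PMN) per the labels. Animals with subclinical endometritis (n = 6), a uterine inflammation without outward signs, had 20 to 52%. Each cow gave 1 array of caruncular endometrium, the raised areas where the placenta attaches, and 1 array of intercaruncular endometrium, the glandular lining between them. Every array measured its sample against 1 pool of all samples, so values are log2 ratios of sample over pool. Between 74.7% and 82.3% of probes were well above background in the sample channel, and the number of arrays limits the precision. Numbers after ± are standard errors of the limma fit over 6 animals per group (12 animals between the tissues), unless SD is written. Progesterone was over 1 ng/ml in 1 control cow and 3 cows with endometritis.

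Before the comparisons, it was checked whether the arrays of each cow resembled each other. For this 150 probes were used whose levels, centred within each tissue, fell into separate clusters. They were chosen without the animal and disease labels. On these probes 9 of the 12 intercaruncular arrays correlated best with the caruncular array of their own cow. Across probes r was 0.639 to 0.954 for these 9. Over all probes the intercaruncular array of endometritis 1 instead correlated best with the caruncular array of control 2, while the other best matches were the same. The intercaruncular arrays labelled control 2, endometritis 5 and endometritis 6 correlated with their own caruncular arrays at r = -0.554, -0.172 and 0.097. Their closest caruncular arrays were those of endometritis 4 (r = 0.91), control 3 (r = 0.93) and control 4 (r = 0.914), each a cow of the other disease group than the label, and none of these shared a slide with its match. PENK, which encodes an opioid precursor, was at 3.69 on the caruncular and -5.09 on the intercaruncular array labelled control 2, and PDZK1, a scaffold protein of membrane transporters, at 1.95 and -5.01. The labels were kept. The comparison within caruncular arrays did not use these 3 arrays, and counts are also given without the 3 animals.

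**Figure D1:**
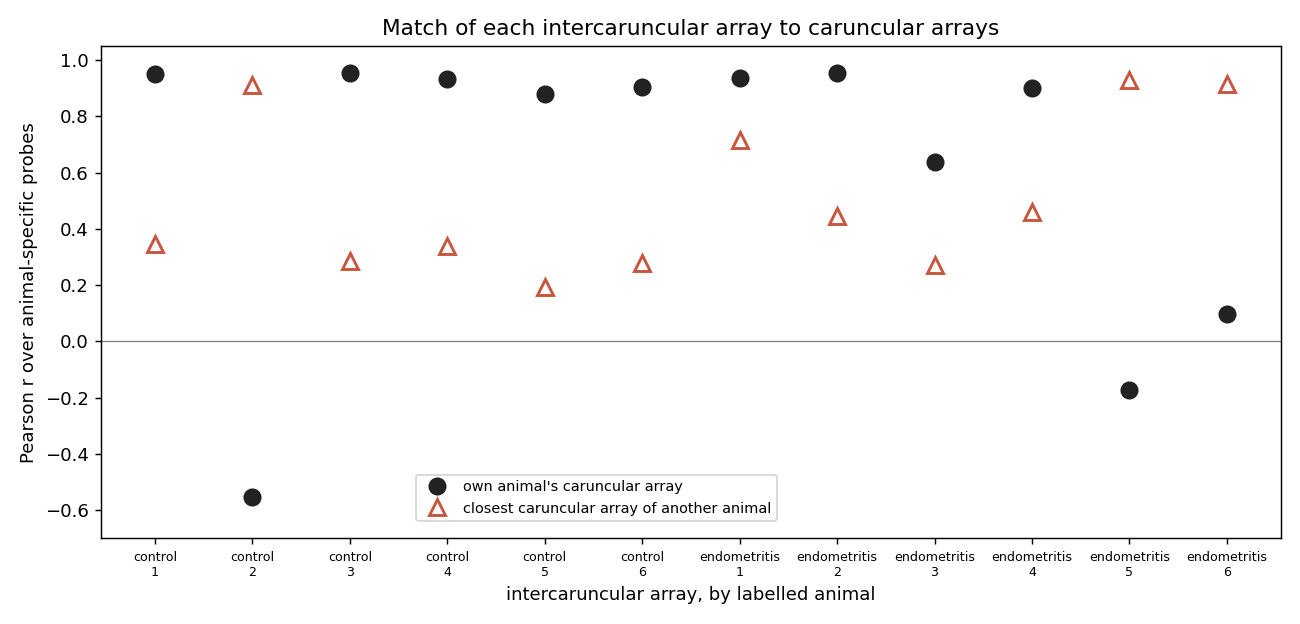
Pearson correlation across 150 probes (y axis) of each intercaruncular array (x axis, by labelled animal) with its own cow's caruncular array (filled circles) and with the closest caruncular array of another cow (open triangles). The circles of 9 cows lie between 0.639 and 0.954, while for control 2, endometritis 5 and endometritis 6 the triangles lie at 0.91 to 0.93 and the circles at 0.097 or lower.

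The first comparison asked which genes differ between cows with subclinical endometritis and control cows when both tissues of a cow are averaged. CTSD, the lysosomal protease cathepsin D, had the smallest p: its mean was -0.20 ± 0.21 (SD, n = 6) in endometritis and 0.38 ± 0.14 (SD, n = 6) in control cows. The difference was -0.58 ± 0.10, with 6 of 6 endometritis cows below the control mean. ARRDC3, an arrestin-domain adaptor protein, differed by -0.30 ± 0.07, ZCCHC10 by 0.45 ± 0.11 and FAIM2, an inhibitor of Fas-mediated death, by -0.62 ± 0.16. RHOB, a small GTPase of endosomes, differed by -0.58 ± 0.13 with 4 endometritis cows measured. None of these passed: limma with Benjamini-Hochberg adjustment called 0 of 22511 genes (smallest adjusted p = 0.865), and 933 genes (4.15%) had an unadjusted p under 0.05. Without the 3 doubted cows limma again called 0, with 2769 genes at an unadjusted p under 0.05. With the slide as a fixed block the count was 0, with 1052 at an unadjusted p under 0.05, and within the 4 slides that held both groups it was 0, with 750.

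No member of any of the 25 gene lists passed over all genes in this comparison, so list members are given as values. T and NK cell markers were higher in endometritis for 23 of 27 members, with a median difference of 0.25 (camera adjusted p = 0.000824, and adjusted p = 0.794 with an estimated correlation). The co-stimulatory receptor ICOS differed by 1.14 ± 0.54 and the lymph node homing receptor CCR7 by 0.84 ± 0.44. Of B and plasma cell markers 10 of 12 were higher (median 0.68, camera adjusted p = 0.000872, and adjusted p = 0.794 with an estimated correlation). Among them were XBP1, a regulator of antibody secretion, at 0.76 ± 0.24 and the B cell coactivator POU2AF1 at 1.75 ± 0.85. Cytokines and chemokines were higher for 26 of 36 members (median 0.29, camera adjusted p = 0.00784, and adjusted p = 0.809 with an estimated correlation). The neutrophil attractant CXCL5 differed by 2.42 ± 1.17 and IL10 by 0.22 ± 0.11. Neutrophil markers (15 of 23 higher, median 0.067, mean 0.43) and antimicrobial and acute phase genes (19 of 24 higher, median 0.61) were not called, at camera adjusted p = 0.12 and 0.0561. Within these lists S100A9 and S100A8, the subunits of calprotectin, differed by 1.84 ± 1.10 and 2.16 ± 1.39, the gelatinase MMP9 by 1.41 ± 0.92, and LAP, a beta-defensin, by 3.25 ± 1.61. On the 4 mixed slides the T and NK list differed by -0.056, 0.50, 0.45 and 0.95, and the B and plasma cell list by -0.057, 0.14, 1.12 and 1.83. The T and NK call ended without endometritis 2 (median 0.098, adjusted p = 0.0865), and its median was 0.41 without the 3 doubted cows. The cytokine call ended without endometritis 2 (0.255, adjusted p = 0.107) or 3 (0.16, adjusted p = 0.171), and its median was 0.156 without endometritis 4.

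Monocyte and macrophage markers were lower for 13 of 18 members (median -0.16, camera adjusted p = 0.0367, and adjusted p = 0.809 with an estimated correlation). Adjusted over the list alone 2 fell: GPNMB, a glycoprotein of lipid-laden macrophages, at -1.52 ± 0.44 and VSIG4, a complement receptor of resident macrophages, at -0.72 ± 0.21. Lower lists of tissue structure were extracellular matrix (26 of 31 lower, median -0.27, camera adjusted p = 0.000162), stromal fibroblast (16 of 22, -0.21, adjusted p = 0.0162), ciliated cell (13 of 14, -0.25, adjusted p = 0.0367) and smooth muscle genes (12 of 16, -0.11, adjusted p = 0.0441). They were at adjusted p = 0.794, 0.794, 0.809 and 0.794 with an estimated correlation. The basement membrane genes NID1 and COL4A1 differed by -0.65 ± 0.21 and -0.47 ± 0.19, the stromal filament VIM by -0.74 ± 0.26 and the Wnt inhibitor SFRP4 by -0.83 ± 0.33. Oxidative phosphorylation genes were higher for 32 of 37 members by a small median of 0.15 (camera adjusted p = 3.94e-07, and adjusted p = 0.794 with an estimated correlation), with NDUFA4 at 0.30 ± 0.09. Ribosomal protein genes were lower for 30 of 40, by a median of -0.044 (camera adjusted p = 0.0336, and adjusted p = 0.809 with an estimated correlation). Without the 3 doubted cows the macrophage, ciliated and smooth muscle calls ended, at adjusted p = 0.0871, 0.0823 and 0.249. With each of the 12 cows left out in turn the macrophage call ended 5 times (median -0.010 without endometritis 1, and -0.27, called, without endometritis 4) and the stromal call 2 times (-0.099 without endometritis 3). The ciliated call ended 6 times (-0.052 without control 1, and -0.43, called, without control 3), the smooth muscle call 6 times (-0.068 without endometritis 6) and the ribosomal call 6 times (-0.017 without control 1, and -0.069, called, without control 2), while the matrix list was at -0.16 without endometritis 3 and the oxidative phosphorylation list at 0.054 with the slide as a fixed block, both called. In cows under 1 ng/ml of progesterone the macrophage, matrix and stromal calls ended (medians 0.055, -0.012 and -0.11) and the direction of the smooth muscle test turned (0.031), as did that of the ribosomal test with processed signals (-0.013).

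The remaining lists were not called with both tissues averaged, at camera adjusted p from 0.172 to 0.838. Their medians were 0.029 for pattern recognition and NF-kB, 0.054 for complement, -0.20 for interferon-stimulated, 0.14 for antigen presentation, 0.11 for epithelium, 0.097 for uterine gland and -0.086 for endothelial genes. They were -0.031 for cell cycle, -0.035 for steroid receptor and progesterone-responsive, 0.095 for prostaglandin, -0.071 for immediate early and heat shock and 0.021 for erythrocyte genes. Matrix remodelling proteases had a median of -0.021 and a mean of 0.12 while the test pointed down, and CTSD fell in this list when adjusted over the list alone. The estrogen receptor gene ESR1 differed by -0.059 ± 0.13, the oxytocin receptor gene OXTR by -0.83 ± 0.69, IGFBP1, a binding protein of insulin-like growth factors, by -1.76 ± 0.56, and PLA2G7, a phospholipase that degrades platelet-activating factor, by -0.40 ± 0.12.

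In caruncular endometrium alone, T and NK cell markers were higher in endometritis for 25 of 27 members, with a median difference of 0.55, and 10 rose when adjusted over the list alone. ICOS rose on that basis by 1.70 ± 0.50, from -1.07 ± 0.66 (SD, n = 6) in control to 0.63 ± 1.18 (SD, n = 6) in endometritis cows. So did CD3G, a chain of the T cell receptor complex, by 0.86 ± 0.28 and SH2D1A, a signalling adaptor, by 0.67 ± 0.22. The list was called by camera at adjusted p = 4.83e-09, and at adjusted p = 0.661 with an estimated correlation. Within the 4 mixed slides it differed by 0.17, 0.51, 0.77 and 0.95. B and plasma cell markers were higher for 10 of 12 members (median 1.01, camera adjusted p = 5.23e-05, and adjusted p = 0.661 with an estimated correlation). POU2AF1 differed by 2.62 ± 0.96, MZB1, a chaperone of antibody secretion, by 2.05 ± 0.78 and XBP1 by 1.11 ± 0.34. On the same slides this list differed by 0.32, 0.59, 1.49 and 2.67.

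Neutrophil markers in caruncular endometrium were higher for 18 of 23 members (median 0.21, mean 0.68, camera adjusted p = 0.0058, and adjusted p = 0.703 with an estimated correlation). S100A8 was at -1.51 ± 3.48 (SD, n = 6) in endometritis and -4.46 ± 1.04 (SD, n = 6) in control cows, a difference of 2.94 ± 1.35 with 4 of 6 endometritis cows above the control mean. S100A9 differed by 2.40 ± 1.09. Cytokines and chemokines (27 of 36 higher, median 0.47, camera adjusted p = 0.000554), antimicrobial and acute phase genes (20 of 24, 0.56, adjusted p = 0.00397) and antigen presentation genes (16 of 21, 0.26, adjusted p = 0.0176) were called higher. Their values were adjusted p = 0.661, 0.661 and 0.703 with an estimated correlation. CXCL5 differed by 3.66 ± 1.28, CXCL2 by 2.39 ± 0.94, LAP by 4.28 ± 1.48, the iron-binding lactoferrin gene LTF by 1.86 ± 0.70 and the elastase inhibitor PI3 by 2.33 ± 0.91. IL12A, a subunit of interleukin 12, was at -0.73 ± 0.29. On the 4 mixed slides the neutrophil list differed by -0.66, 0.33, 0.70 and 0.82, and the cytokine list by -0.26, 0.63, 1.04 and 1.39. Both were lower in endometritis on 1 slide. The neutrophil call ended without endometritis 3 (median 0.084, adjusted p = 0.0601) or 4 (0.037, adjusted p = 0.144), and its median was 0.14 without control 2 and 0.32 without endometritis 1. The cytokine median was 0.285 without endometritis 3 and 0.23 without endometritis 4, both called, and the antimicrobial median 1.048 without the 3 doubted cows. With each cow left out in turn the antigen presentation call ended 4 times (0.14 without control 6, and 0.40, called, without endometritis 1).

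All 14 ciliated cell genes were lower in caruncular endometritis (median -0.43, camera adjusted p = 0.000666), as were 26 of 31 extracellular matrix genes (-0.38, adjusted p = 0.000515) and 15 of 16 smooth muscle genes (-0.23, adjusted p = 0.0149), each at adjusted p = 0.661 with an estimated correlation. ELN, which encodes elastin, differed by -0.41 ± 0.13, FBN1, the microfibril protein fibrillin, by -0.41 ± 0.15 and the axonemal gene CCDC113 by -1.44 ± 0.67. Without control 1 the ciliated median was -0.24 (adjusted p = 0.0422). The matrix list was lower on 4 of 4 mixed slides, by -0.52, -0.25, -1.19 and -0.40. Oxidative phosphorylation genes were higher for 31 of 37 members (median 0.13, camera adjusted p = 0.000116, and adjusted p = 0.661 with an estimated correlation), with NDUFA2 at 0.34 ± 0.10. This call ended with the slide as a fixed block (median 0.012, adjusted p = 0.217), and the smooth muscle call ended in cows under 1 ng/ml of progesterone (-0.19, adjusted p = 0.185) and with 3 of the 12 cows left out singly (-0.15 without control 1). The other 15 lists were not called, and 3 of them held members that passed adjusted over the list alone. The chaperone HSPA8 rose by 0.43 ± 0.12 and the nuclear receptor NR4A2 fell by 0.45 ± 0.12 among immediate early and heat shock genes, CTSD fell by 0.64 ± 0.14 among proteases, and GPNMB fell by 1.76 ± 0.44 among macrophage markers. Macrophage markers had a median of 0.079, a mean of -0.043 and a test pointing down, and epithelium markers a median of 0.049 and a mean of -0.026. IGFBP1 differed by -2.39 ± 0.73, MSTN, an inhibitor of muscle growth, by -1.14 ± 0.30, ESR1 by -0.10 ± 0.17 and OXTR by -0.53 ± 0.68.

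Over all genes, limma called 0 of 22511 in caruncular endometrium (smallest adjusted p = 0.44), and 2336 genes (10.4%) had an unadjusted p under 0.05. The smallest p were those of ID3, an inhibitor of basic helix-loop-helix factors, at -0.46 ± 0.08, ZCCHC10 at 0.61 ± 0.11, the autophagy gene GABARAPL1 at -0.84 ± 0.15, EEF1E1, a subunit of the tRNA synthetase complex, at 0.44 ± 0.08 and NANS, an enzyme of sialic acid synthesis, at 0.75 ± 0.14. Without the 3 doubted cows the limma count was 0 with 2925 at an unadjusted p under 0.05. With the slide as a fixed block it was 0 with 2543, and within the mixed slides 0 with 1762.

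**Figure D2:**
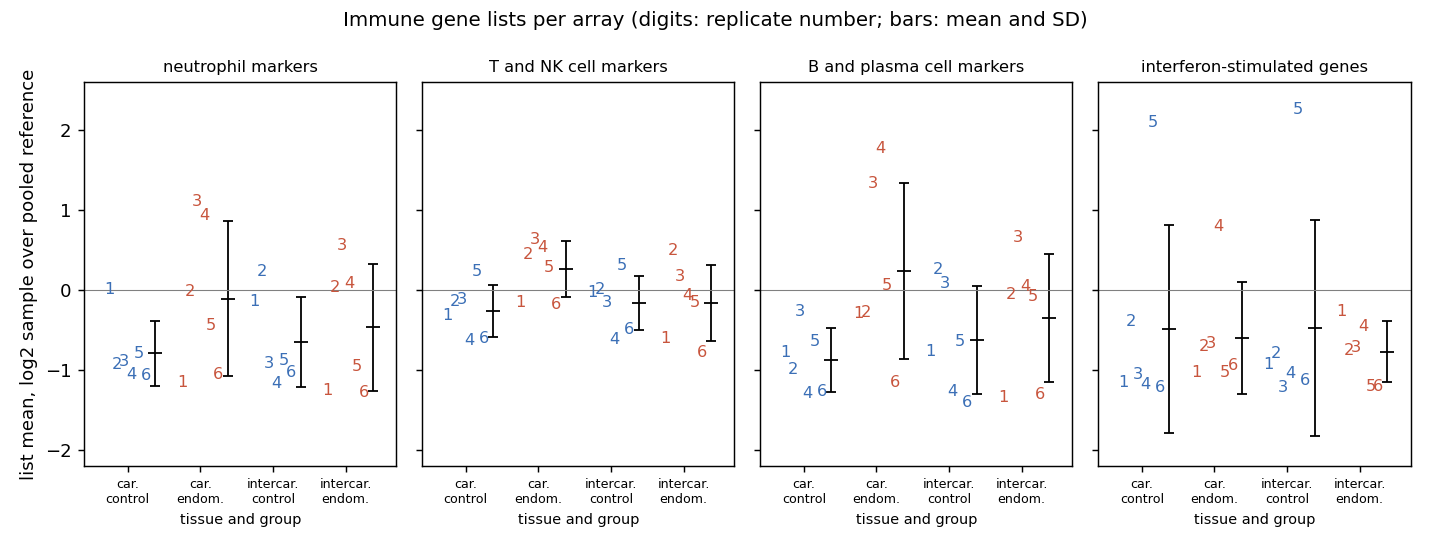
Mean log2 ratio of sample over pooled reference (y axis) of 4 immune gene lists on each array, by tissue and group (x axis). Digits are the replicate numbers of the cows and bars show the mean and SD of 6 arrays; control 5 stands at 2.1 and 2.26 in the interferon-stimulated list.

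In intercaruncular endometrium, monocyte and macrophage markers were lower in endometritis for 17 of 18 members, with a median difference of -0.36 (camera adjusted p = 1.76e-06, and adjusted p = 0.723 with an estimated correlation). The fractalkine receptor CX3CR1 differed by -0.62 ± 0.22, VSIG4 by -0.82 ± 0.32 and CSF1R, the receptor of macrophage colony-stimulating factor, by -0.76 ± 0.29. On the 4 mixed slides the list differed by -1.40, -0.14, 0.019 and 0.20, and in cows under 1 ng/ml of progesterone the call ended (median -0.11, adjusted p = 0.2). Without endometritis 1 the median was -0.16 (adjusted p = 0.00257). Interferon-stimulated genes were lower for 21 of 22 members (median -0.26, camera adjusted p = 0.0212, and adjusted p = 0.839 with an estimated correlation). On those slides they were higher in endometritis, by 0.54, 0.037, 0.58 and 0.56, and without control 5 their direction turned, at a median of 0.22. The call ended without control 2 (-0.35), endometritis 5 (-0.19) or endometritis 6 (-0.22), and the median was -0.43 without control 3 and -0.41 without control 6. Control 5 had list means of 2.10 and 2.26 on its caruncular and intercaruncular arrays, while the other controls were at -0.39 or lower. The T and NK list was at a median of 0.023 and the neutrophil list at 0.022. The neutrophil mean was 0.18, with a camera test pointing down (adjusted p = 0.682). These medians include the 3 doubted arrays, each closest to a cow of the other disease group, which can shrink a group difference. The neutrophil list mean was 0.235 on the array labelled control 2 (other controls -1.17 to -0.146). It was -0.961 and -1.283 on those labelled endometritis 5 and 6 (others -1.257 to 0.558). So these medians alone do not show a contrast to caruncular tissue.

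Lower in intercaruncular endometritis were also extracellular matrix genes (27 of 31, median -0.13, camera adjusted p = 0.00364), stromal fibroblast genes (16 of 22, -0.25, adjusted p = 0.0212), matrix remodelling proteases (19 of 27, -0.12, adjusted p = 0.0151) and ribosomal protein genes (32 of 40, -0.040, adjusted p = 0.0212). Epithelium genes (20 of 24, 0.18, adjusted p = 0.0151) and oxidative phosphorylation genes (34 of 37, 0.14, adjusted p = 1.76e-06) were higher. All 6 were at an adjusted p of 0.723 or 0.839 with an estimated correlation. In cows under 1 ng/ml of progesterone the medians were 0.29 for matrix genes, 0.080 for proteases and 0.0050 for epithelium genes, with the direction of all 3 tests turned, and the stromal (-0.14) and ribosomal (-0.068) calls ended. With the slide as a fixed block the stromal (-0.075, adjusted p = 0.489) and epithelium calls (0.19, adjusted p = 0.271) ended. With each cow left out in turn the matrix call ended 4 times (-0.032 without endometritis 1, and -0.24, called, without control 5), the protease call 4 times (-0.025 without endometritis 6, and -0.195, called, without endometritis 5) and the epithelium call 3 times (0.045 without endometritis 3). The stromal call ended 6 times (-0.16 without endometritis 1) and the ribosomal call 6 times (-0.0090 without control 1, and -0.091, called, without control 2), and the oxidative phosphorylation median was 0.093 without control 5. VIM differed by -0.80 ± 0.32, IHH, the hedgehog signal of uterine epithelium, by 0.91 ± 0.41 and the aldose reductase gene AKR1B1 by 1.41 ± 0.62. The other 17 lists were not called, and no list had a member past the threshold adjusted over the list alone. The smallest p of single genes were those of MPTX1, a pentraxin, at 2.08 ± 0.47, SPON2, a matrix protein that binds bacteria, at -0.40 ± 0.10, FOLR2, a folate receptor of macrophages, at -0.70 ± 0.18, MARCKS at -0.30 ± 0.08 and the apoptosis activator BMF at -0.27 ± 0.07. ESR1 differed by -0.016 ± 0.12 and OXTR by -1.13 ± 0.75. Over all genes limma called 0 (smallest adjusted p = 1.0, 550 or 2.44% at an unadjusted p under 0.05), and without the 3 doubted arrays 0 with 2183. The interferon, protease and stromal calls ended without those arrays, at adjusted p = 0.598, 0.166 and 0.158. With the slide as a fixed block 0 genes were called with 676 at an unadjusted p under 0.05, and within the mixed slides 0 with 524.

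The design also asked whether the tissues responded differently, tested on each cow's caruncular minus intercaruncular value. The endometritis difference of T and NK cell markers was higher in caruncular endometrium for 27 of 27 members, by a median of 0.57, and 13 rose when adjusted over the list alone. Among these CD247, the zeta chain of the T cell receptor, differed by 0.75 ± 0.15, CD5 by 0.71 ± 0.16, the kinase LCK by 0.67 ± 0.17 and CD2 by 0.57 ± 0.16. Camera called the list at adjusted p = 4.38e-15 and fry at adjusted p = 0.0206, against adjusted p = 0.0798 with an estimated correlation. On the mixed slides this list differed by 0.72, 0.065, 0.45 and 0.44. B and plasma cell markers were higher for 12 of 12 members (median 0.77, adjusted p = 2.71e-06), with CD79A, part of the B cell receptor, at 1.42 ± 0.47. Macrophage markers were higher for 16 of 18 (0.32, adjusted p = 5.53e-05), neutrophil markers for 19 of 23 (0.32, adjusted p = 4.79e-05) and cytokines for 30 of 36 (0.33, adjusted p = 8.72e-06). Adjusted over the list alone, 2 neutrophil markers rose, among them ALOX5AP, which activates leukotriene synthesis, by 1.04 ± 0.27, and the T cell attractant CCL5 was at 0.88 ± 0.31. The B cell and cytokine lists were at adjusted p = 0.44 and the neutrophil list at adjusted p = 0.454 with an estimated correlation, and the macrophage list was not called either. Without the 3 doubted cows, whose intercaruncular arrays matched cows of the other disease group, these 5 lists were called again, at medians of 0.48 for T and NK, 0.61 for B and plasma cell, 0.46 for macrophage, 0.26 for neutrophil and 0.29 for cytokine genes. The neutrophil median was 0.19 without control 2, and the macrophage and cytokine medians 0.20 and 0.19 without endometritis 4.

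Antigen presentation genes had a higher difference in caruncular tissue for 19 of 21 members (median 0.39, adjusted p = 8.72e-06, and adjusted p = 0.454 with an estimated correlation). The invariant chain gene CD74 rose by 0.55 ± 0.14 adjusted over the list alone, and BOLA-DRA was at 0.63 ± 0.19. Complement genes followed for 19 of 26 members (0.36, adjusted p = 0.000232, and adjusted p = 0.44 with an estimated correlation), with CFD, complement factor D, rising by 0.63 ± 0.13 adjusted over the list alone and C3 at 0.99 ± 0.32. Interferon-stimulated genes (20 of 22 higher, 0.15, adjusted p = 0.0223) and ciliated cell genes (14 of 14 lower, -0.37, adjusted p = 0.0145) were both at adjusted p = 0.817 with an estimated correlation. The interferon list was higher on 1 of the 4 mixed slides and the ciliated list lower on 4 of 4. The antigen presentation (median 0.33), complement (0.23), interferon (0.23) and ciliated lists (-0.22) were called again without the 3 doubted cows. The complement median was 0.19 without control 2 and the antigen presentation median 0.24 without endometritis 6, both called. The ciliated call ended without endometritis 6, whose intercaruncular array is doubted (median -0.084, adjusted p = 0.599), and without control 3 (-0.295, adjusted p = 0.0774). Its median was -0.59 without endometritis 5, and -0.018 in cows under 1 ng/ml of progesterone with the direction of the test turned. The interferon call ended without control 1, 4 or 5 (0.12, 0.14 and 0.12), the direction of its test turned without endometritis 4 (-0.035), and its median was 0.345 without endometritis 1. The other 16 lists were not called, with prostaglandin (median 0.064, mean -0.078), immediate early (0.012 and -0.072) and erythrocyte genes (test pointing up at a median of -0.030) differing in sign. Limma called 0 single genes (smallest adjusted p = 0.584, 1679 or 7.46% at an unadjusted p under 0.05), and 0 with 1745 without the 3 doubted cows. The smallest p were those of TIMD4, a phosphatidylserine receptor (caruncular minus intercaruncular 0.71 ± 0.33, SD, n = 6, in endometritis and -0.33 ± 0.42 in control cows), C16H1orf116 at 0.90 ± 0.18, CFD, CD247 and CCDC88B at 0.84 ± 0.18, while ESR1 was at -0.085 ± 0.15 and OXTR at 0.60 ± 0.37.

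Caruncular and intercaruncular endometrium were compared within cows, and here many genes changed. CXCL14, a chemokine of epithelium and stroma, was higher in caruncular tissue by 2.11 ± 0.19 in 12 of 12 cows (limma adjusted p = 0.000513). MASP1, a protease of the lectin pathway of complement, was higher by 2.21 ± 0.38 in 11 of 12 and the Wnt inhibitors SFRP4 by 1.86 ± 0.33 and DKK2 by 1.75 ± 0.26, each in 11 of 12. Also higher were CCDC73 (2.04 ± 0.26), CBLN2 (1.97 ± 0.36), SPP1, the secreted glycoprotein osteopontin (1.45 ± 0.36, 10 of 12 cows), TF, transferrin (1.42 ± 0.31), the muscarinic receptor CHRM2 (1.29 ± 0.17, 12 of 12) and PTN, pleiotrophin (1.28 ± 0.21). CLDN10, a tight junction protein of epithelium, was lower in caruncular tissue by -2.51 ± 0.43 in 12 of 12 cows (adjusted p = 0.0037), IHH by -1.97 ± 0.35 in 11 of 12 and the homeobox gene BARX2 by -1.94 ± 0.23 in 12 of 12 (adjusted p = 0.000867). SMPX (-2.31 ± 0.46), MPTX1 (-2.29 ± 0.41) and the genes of cilia and flagella HOATZ (-2.15 ± 0.41), ERICH2 (-1.91 ± 0.30), CFAP144 (-1.88 ± 0.34), CFAP141 (-1.84 ± 0.35) and CCDC113 (-1.83 ± 0.39) were lower as well. In all, limma called 3202 of 22511 genes, 1614 higher and 1588 lower in caruncular tissue, of which 1493 had a symbol (707 and 786). Without the 3 doubted cows it called 2688, and 1093 of these were higher. Caruncular arrays lay at other positions of the slides than intercaruncular arrays, so position and tissue cannot be told apart.

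Of 24 epithelium markers 17 fell in caruncular tissue (20 adjusted over the list alone) and 7 did not pass, with a median of -0.64. The keratin KRT18 fell by 0.94 ± 0.12, the splicing factor ESRP1 by 0.76 ± 0.12 and the mucin MUC1 by 1.04 ± 0.17. Of 14 ciliated cell genes 13 fell (14 adjusted over the list alone), with a median of -0.97, among them SPAG6 (-1.46 ± 0.27), DNAAF11 (-1.12 ± 0.16) and DNAH7 (-0.98 ± 0.18). Among 22 stromal fibroblast markers 9 rose and 13 did not pass (11 rose and 1 fell adjusted over the list alone), with a median of 0.41. The growth factor receptors PDGFRA and PDGFRB rose by 1.00 ± 0.11 and 0.43 ± 0.06. Smooth muscle markers rose for 10 of 16 (12 adjusted over the list alone, median 0.57), with LMOD1 at 0.74 ± 0.11 and CALD1 at 0.55 ± 0.09. Endothelial markers rose for 7 of 20 (8 adjusted over the list alone, median 0.19), with ENG at 0.40 ± 0.04 and the tight junction gene CLDN5 at 0.56 ± 0.10. Camera called these 5 lists at adjusted p = 1.19e-11, 3.55e-10, 0.000166, 1.8e-05 and 0.000126, and fry at adjusted p = 0.00552, 0.00552, 0.000716, 0.00624 and 0.0159. With an estimated correlation they were at adjusted p = 0.394, 0.394, 0.265, 0.394 and 0.455. Stromal markers were higher in 12 of 12 cows, smooth muscle markers in 11 and endothelial markers in 9, while epithelium and ciliated markers were lower in 11 of 12 each.

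**Figure D3:**
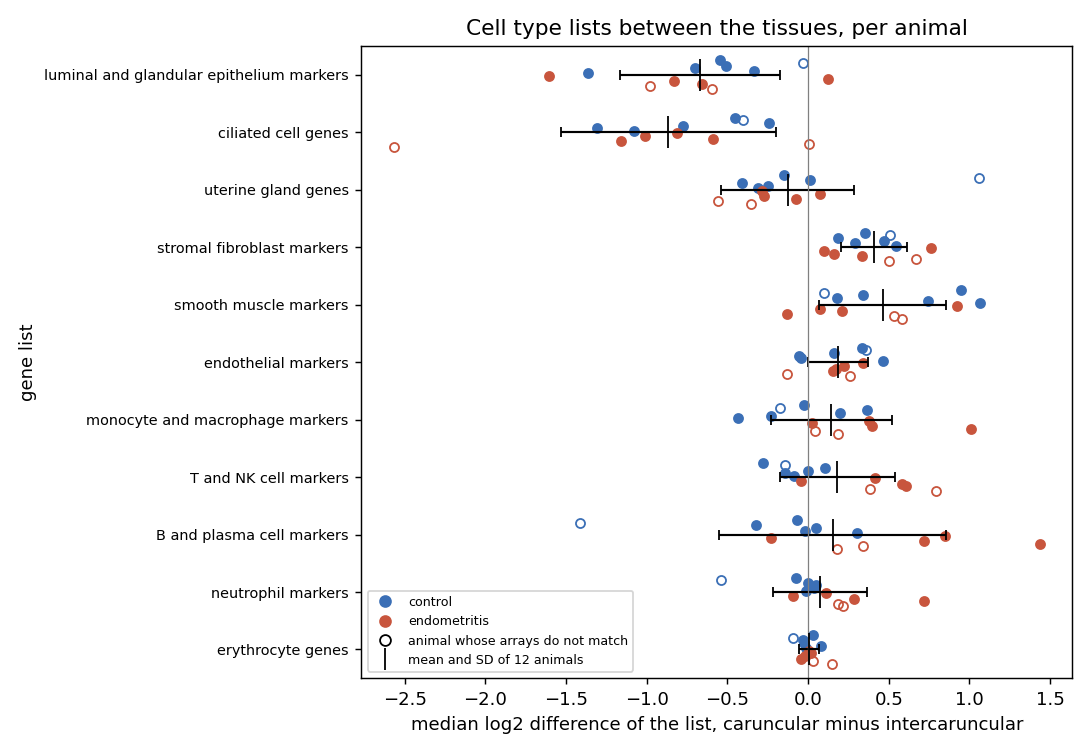
Median log2 difference of each cell type list between the tissues (x axis, caruncular minus intercaruncular) for each of 12 cows (points), by list (y axis), with open points for the 3 cows whose arrays were unlike each other and bars for the mean and SD. Stromal markers lie above 0 in 12 of 12 cows (mean 0.41, SD 0.20) and ciliated markers below 0 in 11 of 12 (mean -0.87, SD 0.67).

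Further lists differed between the tissues in part. Matrix remodelling proteases rose for 6 of 27 members (9 adjusted over the list alone, median 0.28, camera adjusted p = 0.00521, and adjusted p = 0.403 with an estimated correlation). The aggrecanase ADAMTS5 rose by 0.53 ± 0.10 and MMP2 by 0.40 ± 0.11. Extracellular matrix genes rose for 6 of 31 (7 rose and 1 fell adjusted over the list alone, median 0.12, adjusted p = 0.0139), with MFAP4 at 0.67 ± 0.10 and BGN, biglycan, at 0.79 ± 0.12. Pattern recognition and NF-kB genes rose for 4 of 31 (4 adjusted over the list alone, 0.058, adjusted p = 0.0165), with the RNA sensor TLR3 at 0.39 ± 0.09. Cytokines rose for 3 of 36 (2 adjusted over the list alone, 0.13, adjusted p = 0.0292), namely IL1A at 1.06 ± 0.28, CXCL12 at 0.91 ± 0.24 and CCL11 at 0.70 ± 0.22. T and NK markers rose for 2 of 27 (1 adjusted over the list alone, 0.13, adjusted p = 0.044), namely CD4 at 0.17 ± 0.04 and CD5 at 0.43 ± 0.12. Complement genes rose for 5 and fell for 2 of 26 (7 and 2 adjusted over the list alone, 0.18, adjusted p = 0.046), with C1S at 0.62 ± 0.11, the complement inhibitor SERPING1 at 0.60 ± 0.11 and CFI, factor I, at -1.05 ± 0.18. Of 26 cell cycle genes 1 fell, also when adjusted over the list alone (CCNB1, cyclin B1, at -1.24 ± 0.26, list median -0.15, adjusted p = 0.044). Of 37 oxidative phosphorylation genes 4 fell (0 adjusted over the list alone, median -0.073, adjusted p = 0.00966), such as NDUFV2 at -0.18 ± 0.05. With an estimated correlation the pattern recognition list was at adjusted p = 0.624 and the other 6 of these lists at adjusted p = 0.744. In control cows alone T and NK markers were called lower in caruncular tissue (median -0.066, adjusted p = 0.0323) and the cytokine median was -0.020 with the direction of the test turned, as was that of cell cycle genes without the 3 doubted cows (0.052). With each cow left out in turn the complement call ended 7 times (0.10 without endometritis 4), the T and NK call 5 times (0.092 without endometritis 6), the cell cycle call 5 times (-0.038 without control 2, and -0.27, called, without control 5) and the cytokine call 3 times (0.085 without endometritis 3 or 4). The pattern recognition call ended without endometritis 4 (0.047), and the matrix (0.064) and oxidative phosphorylation calls (-0.050) without endometritis 1.

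The 12 remaining lists were not called between the tissues by camera. Prostaglandin genes rose for 3 and fell for 1 of 22 members (4 and 1 adjusted over the list alone), with the prostaglandin F receptor PTGFR at 1.11 ± 0.20, the synthase PTGDS at 0.72 ± 0.15 and the prostaglandin E receptor PTGER2 at -0.40 ± 0.08. Their median of -0.031 and mean of 0.047 differed in sign. Steroid receptor and progesterone-responsive genes rose for 5 and fell for 3 of 29 (5 and 4 adjusted over the list alone, median 0.039), with the nuclear receptor NR2F2 at 0.68 ± 0.14. Uterine gland genes rose for 1 and fell for 2 of 16 (1 and 2 adjusted over the list alone, -0.091), with GRP, gastrin-releasing peptide, at -1.59 ± 0.23. Antimicrobial and acute phase genes fell for 3 of 24 (3 adjusted over the list alone, -0.0030), namely MUC1, SAA2 at -0.86 ± 0.22 and ITIH4 at -1.22 ± 0.20, for which another probe pointed the other way. B and plasma cell markers rose for 2 of 12 (2 adjusted over the list alone, 0.10), namely PRDM1 at 0.50 ± 0.09 and BLK at 0.51 ± 0.15. Single members passed among macrophage (MS4A7 rose, 0.71 ± 0.17, list median 0.090), interferon-stimulated (IFIT5 rose, 0.25 ± 0.06, 0.12) and erythrocyte genes (HBA rose, 0.22 ± 0.06, -0.048), each also adjusted over its list alone. Of ribosomal protein genes RPLP0 fell (-0.18 ± 0.05, list median -0.040, 0 adjusted over the list alone). Immediate early and heat shock genes rose for 1 (HSPB1) and fell for 1 (HSPD1) of 25 (4 and 2 adjusted over the list alone, -0.026), and of neutrophil (median 0.085) and antigen presentation genes (0.050) 0 passed on either basis. ESR1 differed by -0.013 ± 0.07 and OXTR by -0.60 ± 0.20 (adjusted p = 0.0562).

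Progesterone was the last comparison, fitted as the change per doubling of its concentration with the disease group in the model. The concentrations fell into 2 separate clusters, 0.03 to 0.33 and 2.63 to 9.55 ng/ml. By the plan a slope is then read as high against low, not as a graded response. PDZK1 rose by 0.75 ± 0.10 on the log2 scale per doubling, CRIPTO, a co-receptor of the TGF-beta family, by 0.55 ± 0.08, and TST, a sulfur transferase of mitochondria, by 0.32 ± 0.05. AKR1B1 rose by 0.29 ± 0.04, UGT1A6, an enzyme that conjugates small molecules, by 0.29 ± 0.04 and the glutamate transporter SLC1A1 by 0.19 ± 0.03. All 6 were at a limma adjusted p of 0.0383. Limma called 21 of 22511 genes, all of them positive and 12 with a symbol, and 1738 (7.72%) had an unadjusted p under 0.05. Uterine gland genes rose for 2 of 16 members (CRIPTO and SLC1A1, 4 adjusted over the list alone, median 0.025, camera adjusted p = 0.0107, and adjusted p = 0.529 with an estimated correlation). Prostaglandin genes rose for 1 of 22 (AKR1B1, 4 adjusted over the list alone, 0.024, adjusted p = 0.0359, and adjusted p = 0.529 with an estimated correlation). The others were HPGD, which breaks down prostaglandins, at 0.41 ± 0.07, AKR1C4 at 0.32 ± 0.08 and AKR1C3 at 0.23 ± 0.06. Epithelium genes rose for 3 of 24 adjusted over the list alone (0 over all genes, median 0.054, adjusted p = 0.000719, and adjusted p = 0.643 with an estimated correlation). The opioid precursor PENK (0.75 ± 0.12, adjusted p = 0.0503 over all genes) and ESR2 (0.088 ± 0.02) rose when adjusted over the progesterone-responsive list alone, whose median of -0.0090 and mean of 0.022 differed in sign. ESR1 was at -0.030 ± 0.02 and OXTR at -0.26 ± 0.11. Without the 3 doubted cows limma called 6 genes, and the 5 genes with the largest slopes did not stay past the threshold. With control 2, 3, 4 or 6 or endometritis 4 left out it called 0. It also called 0 with processed signals (smallest adjusted p = 0.0634), with the series matrix (0.0635), without a filter on dim probes (0.0507) and in caruncular arrays alone (0.171), and 1 with array weights. With each cow left out in turn the prostaglandin call ended 5 times (median 0 without endometritis 3) and the uterine gland and epithelium calls 2 times each (0.0020 and 0.025 without endometritis 3, and 0.057 and 0.10, called, without endometritis 2), and the epithelium call ended without the 3 doubted cows (median 0.029, adjusted p = 0.217).

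Several lists fell with progesterone without any member past the threshold over all genes. Extracellular matrix genes were at a median of -0.057 per doubling (camera adjusted p = 0.000719), macrophage markers at -0.053, cell cycle genes at -0.047 (both adjusted p = 0.0035) and cytokines at -0.042 (adjusted p = 0.0196). Below 0 were also stromal fibroblast markers at -0.036 (adjusted p = 0.00804), smooth muscle at -0.033 and T and NK markers at -0.032 (both adjusted p = 0.0107), neutrophil markers at -0.017 (adjusted p = 0.0408) and ribosomal protein genes at -0.014 (adjusted p = 0.000362). Oxidative phosphorylation genes were at 0.016 (adjusted p = 0.00167). With an estimated correlation these lists were at adjusted p from 0.547 to 0.71. With each cow left out in turn the neutrophil call ended 5 times (0 without endometritis 4, and -0.057, called, without endometritis 3), the T and NK call 4 times (-0.0090 without endometritis 2, and -0.066, called, without endometritis 3) and the cytokine call 3 times, and without endometritis 1 the direction of the cytokine test turned (-0.0040). The macrophage call ended without endometritis 1 (-0.011, adjusted p = 0.358) or 4 (-0.026), the cell cycle call without endometritis 1 (-0.0080) or 4 (-0.0040, adjusted p = 0.688) and the smooth muscle call without endometritis 3 or 4 (-0.029 in both). The matrix (-0.032) and stromal calls (-0.032) ended without endometritis 3 and the oxidative phosphorylation call without control 2 (0.0080), and the ribosomal median was -0.0090 without control 2 or endometritis 2. PDGFRB, at -0.078 ± 0.02, was the only member of these lists that passed adjusted over its list alone. The other 12 lists were not called.

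**Figure D4:**
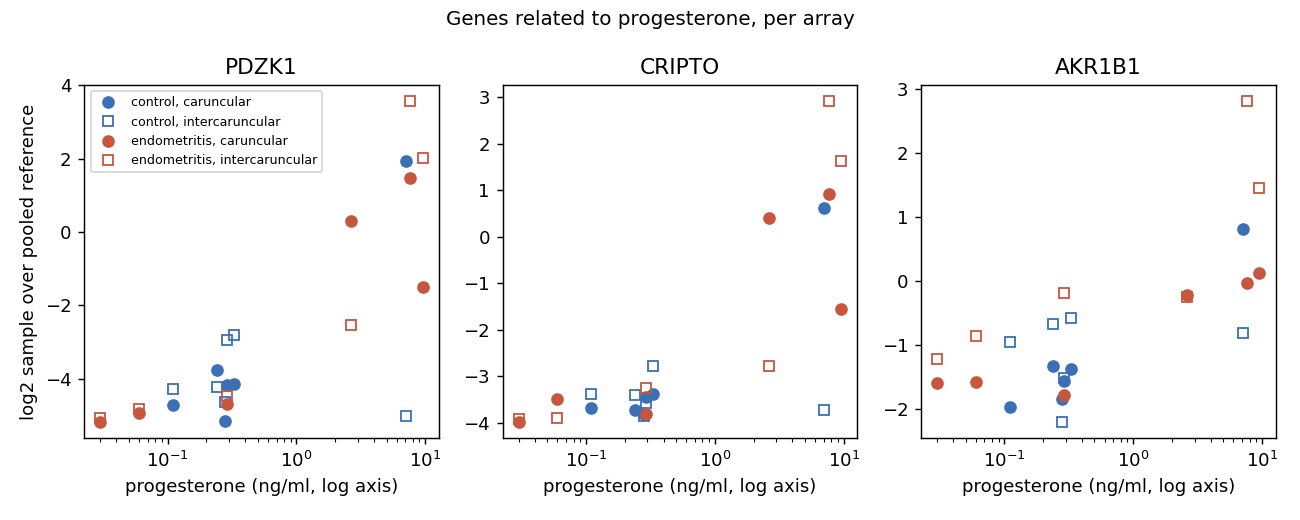
Log2 ratio of sample over pooled reference (y axis) of PDZK1, CRIPTO and AKR1B1 on each array against the progesterone concentration of the cow (x axis, ng/ml, log axis), for caruncular (circles) and intercaruncular arrays (squares) of control and endometritis cows. The caruncular array of control 2, at 7.08 ng/ml, stands at 1.95 for PDZK1 and the intercaruncular array with that label at -5.01.

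Across the 6 cows with endometritis, the mean of 23 neutrophil markers was set against the PMN percentage of the labels. With both tissues averaged Pearson's r was 0.53 (exact permutation p = 0.236, both sides) and Spearman's rho 0.486 (exact permutation p = 0.356). Without the 2 cows farthest from the median PMN r was 0.755. Caruncular arrays alone gave r = 0.626 (exact permutation p = 0.189) and rho 0.486 (r without the 2 farthest 0.852). Intercaruncular arrays alone gave r = 0.398 (exact permutation p = 0.406) and rho 0.371 (exact permutation p = 0.497). The relation with both tissues averaged was the planned 1, and none of the 3 passed. The averaged and intercaruncular relations include the doubted arrays of endometritis 5 and 6, which were closest to control 3 and control 4. A weak relation there therefore does not show that none exists. The cows with the highest caruncular neutrophil means were endometritis 3 and 4.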

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

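The tests of the 3 doubted arrays, of control 5, of array position and of the share of epithelium were chosen only after the results were seen. Among 292 groups of 6 arrays tested, 19 held an array far from the others, and chance flags about 1 in 20 groups.

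Interferon-stimulated genes were far above the other controls in control 5, with a list mean of 2.1 on the caruncular array (others -1.22 to -0.39) and 2.26 on the intercaruncular array (others -1.23 to -0.80). MX1 was at 3.48 and 3.43 on these arrays, where the next highest cows were at 0.51 and -0.64, and ISG15 was at 2.90 and 3.05. A few genes were not the source, since control 5 was the highest cow in both tissues for 21 of 22 members. A slide effect was argued against by control 6, which lay on the same slide at -1.225. An interferon response of this animal may explain the rise in both tissues, which was not tested since the design has no group for it. In caruncular tissue endometritis 4 stood out in the same list at 0.798 (others -1.04 to -0.66).

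On the caruncular array of control 2, genes related to progesterone were far above the other controls: PDZK1 at 1.948 (others -5.16 to -3.78), CRIPTO at 0.614 (-3.82 to -3.40), TST at 1.544 (-1.56 to -0.70) and AKR1B1 at 0.816 (-1.98 to -1.33). Control 2 was the only control over 1 ng/ml of progesterone. The progesterone genes were named for their slope in these same data, so their high values in this cow follow in part from that choice. CTSD was at 1.085 (0.37 to 0.59) and the ribosomal protein list at 0.004 (0.11 to 0.17) on this array, and on the intercaruncular array with this label EEF1E1 was at 0.257 (-0.54 to -0.29).

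The intercaruncular arrays labelled control 2, endometritis 5 and endometritis 6 were unlike the caruncular arrays of their cows. All 3 correlated with a caruncular array of another cow more highly (r from 0.91 to 0.93) than any 2 arrays of different cows did on the same 150 probes without these arrays (at most 0.717), as a wrong label would give. Among intercaruncular arrays the highest r on these probes was 0.977, and 0.437 without the 3 arrays. The labels argue against a similar hormone state for control 2 and endometritis 4 (7.08 and 0.06 ng/ml of progesterone) and for endometritis 6 and control 4 (2.63 and 0.33). For endometritis 5 and control 3 (0.29 and 0.24) it stays open. A similar neutrophil state is not excluded, though the PMN percentages of the labels were 0 and 48, 27 and 0, and 52 and 0 in these pairs. The 150 probes include CXCL8 and LAP, which rose with the bacteriology score, and PDZK1 and CRIPTO, which rose with progesterone. Over all probes the 3 arrays kept their closest cows. There the intercaruncular array of endometritis 1 (7.66 ng/ml) was closest to the caruncular array of control 2 (7.08 ng/ml). A shared slide was argued against since 0 of the 3 lay on the slide of the cow they resembled. At which step a wrong label may have arisen was not tested. On the caruncular array of control 2, at 7.08 ng/ml of progesterone, PENK, PDZK1, CRIPTO, UGT1A6 and AKR1B1 stood above the cows under 1 ng/ml. On its intercaruncular array they lay among those cows (PDZK1 at 1.95 and -5.01). For endometritis 6, at 2.63 ng/ml, the genes disagreed. PENK was at -3.81 on the caruncular array, among those cows (-5.93 to -3.54), and at -2.11 on the intercaruncular array, above them (at most -2.91). PDZK1 was at 0.29 and -2.54, CRIPTO at 0.41 and -2.79 and UGT1A6 at -0.42 and 0.44. These lay above those cows on both arrays. For intercaruncular CRIPTO (at most -2.793) and caruncular UGT1A6 (at most -0.452) the margin was small. AKR1B1 was at -0.23, above them, and at -0.26, among them (at most -0.19). Which label of endometritis 6 is at odds with progesterone stays open.

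Single arrays stood apart in further lists and genes. Neutrophil markers were at 0.01 in caruncular control 1 (others -1.08 to -0.80), macrophage markers at -1.07 in intercaruncular endometritis 1 (-0.29 to 0.025), and OXTR at -4.624 on the same array (-1.11 to 0.63). Endometritis 3 stood out in intercaruncular uterine gland genes at 0.598 (-0.94 to -0.63) and DKK2 at -0.434 (-1.62 to -1.21), and in caruncular prostaglandin genes at 0.573 (-0.41 to -0.051) and erythrocyte genes at 0.308 (-0.25 to -0.096). EEF1E1 was at 0.363 in caruncular endometritis 6 (-0.093 to -0.025) and BMF at 0.034 in intercaruncular endometritis 5 (-0.090 to -0.044).

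The endometritis difference was unlike between the tissues for 9 lists, by camera on the difference itself, and all 9 calls were lost with an estimated correlation (adjusted p from 0.0798 to 0.817). The value in caruncular minus that in intercaruncular tissue was above 0 for T and NK (0.571), B and plasma cell (0.766), neutrophil (0.325), macrophage (0.324), cytokine (0.326), complement (0.359), antigen presentation (0.392) and interferon-stimulated genes (0.151), and below 0 for ciliated cell genes (-0.374, and -0.084 without endometritis 6), while the interferon difference itself was below 0 in both tissues (-0.147 and -0.263) and the macrophage difference was at 0.079 and -0.363. Of 100 splits of the cows 48 called as many lists (highest other 18), and 17 gave as many genes at an unadjusted p under 0.05 as the 1679 found (highest other 2447), so chance could not be excluded.

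Chance could not be excluded in the disease comparisons either. With both tissues averaged 42 of 100 splits gave as many genes at an unadjusted p under 0.05 as the 933 found (highest other 7080) and 52 called as many lists as the 10 found (highest other 18). In caruncular tissue 12 splits reached the 2336 genes (highest other 4705) and 45 the 10 lists (highest other 20), and in intercaruncular tissue 70 reached the 550 genes (highest other 6545) and 63 the 8 lists (highest other 16). Other splits called up to 2980 genes past the adjusted threshold with both tissues averaged, 2428 in intercaruncular and 1 in caruncular tissue. The real groups called 0 in each. They set each of the 3 doubted intercaruncular arrays against the cow it resembled, which can lower the count, while other splits can join them. The splits were not repeated without these arrays, so counts that use intercaruncular arrays cannot decide on chance. What the splits with many calls share was not tested.

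Between the tissues, 1 of 100 sign changes gave as many genes as the 3202 found, the real 1 itself (highest other 1), so chance was excluded for the genes, while 15 called as many lists as the 13 found (highest other 16), so it could not be excluded for the number of lists. Position on the slide and tissue cannot be told apart, since the design joins them: the reference channel, with 1 RNA at every position, differed between the positions for 4384 genes, yet its differences did not run with those of the ratio (r = 0.015 across genes) and were smaller in the changed genes (median size 0.074 against 0.35). The rule by which the position test was read was rewritten after 4384 was seen. By the first rule this value would have been read as an effect of position. A lower share of epithelium alone would raise all other cell types alike, and smooth muscle markers rose by 0.32 more than macrophage markers (exact sign-flip p = 0.128) and stromal by 0.22 more than endothelial markers (exact sign-flip p = 0.0083, adjusted p = 0.0718 over 28 pairs of cell types). Only pairs with erythrocyte genes passed, stromal markers lying 0.40 above them in 12 of 12 cows (adjusted p = 0.0137), but 1 of the 9 erythrocyte genes was bright, so this explanation stays open, and a different make-up of the tissues is untested. For progesterone 3 of 100 reassignments within the disease groups gave as many genes as the 21 found (highest other 93), so a share under 1 in 20 was reached. Yet the highest called several times the real count, and the reason was not tested.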

How the results depend on the processing

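Tests without the 3 doubted cows, of progesterone in each tissue and of the bacteriology score were chosen only after the results were seen. Over all settings, called lists kept their direction and call 230 times with both tissues averaged (67 lost the call), 267 in caruncular tissue (33), 172 in intercaruncular tissue (62), 291 between the tissues (57), 214 in the interaction (27) and 292 with progesterone (71). Their direction turned 3 times with both tissues averaged, 0 times in caruncular and 6 times in intercaruncular tissue. It turned 3 times between the tissues, 2 in the interaction and 1 with progesterone. The counts include quantile normalization of average signal, which leaves ratios as they were. Named genes did so 545 times between the tissues (39 lost the call) and 98 times with progesterone (83). The 0 genes of the disease comparisons stayed 0 in every setting that kept all cows. With the replicate number as a block, which joins cows of 1 slide for numbers 1 to 4 and cows of different slides for 5 and 6, they were 0, 0 and 0, and it changed no call of genes; own number was the best match only for number 6. Where a value below changed, the cause was not tested.

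The 3202 genes between the tissues ranged from 2688 to 4393 over the settings that kept the animal block (4739 of 36410 probes taken singly), were 805 without the block, 99 in controls only and 264 in endometritis cows only, where fewer cows were tested, and with single cows left out 2200 (control 6) to 4031 (control 2). In controls only the medians of T and NK markers (-0.066) and cytokines (-0.020) turned, and without the 3 doubted cows that of cell cycle genes (0.052).

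The 21 genes related to progesterone were 0 with processed signals (1613 at an unadjusted p under 0.05) and with the series matrix (1601), 47 with scaling, 0 without a filter (2005), 1 with array weights, 39 for over against under 1 ng/ml, 6 without the 3 doubted cows, 0 in caruncular arrays alone (1316) and 175 in intercaruncular arrays without the 3. Leaving out single cows gave 0 (control 2, 3, 4, 6 and endometritis 4) to 45 (endometritis 6), with 1 and 2 without control 1 and 5 and 8, 9 and 3 without endometritis 1, 2 and 3. Cytokines at -0.042 per doubling ranged from -0.096 (without endometritis 3) to -0.004 (without endometritis 1), where the direction of the test turned.

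With single cows left out, the interaction count was 0 to 61 (without endometritis 2), the caruncular count 0 to 1 (without endometritis 6) and the other disease counts 0. Interferon-stimulated genes in intercaruncular tissue, at -0.263, were at 0.353 with the slide as a fixed block and on the 4 mixed slides, and ranged from -0.428 (without control 3) to 0.222 (without control 5). Their interaction ranged from -0.035 (without endometritis 4) to 0.345 (without endometritis 1). Ribosomal protein genes with both tissues averaged were at -0.013 with processed signals and with the series matrix, where the direction of the test turned. In cows under 1 ng/ml of progesterone, smooth muscle markers with both tissues averaged were at 0.031, in intercaruncular tissue matrix genes at 0.287 and proteases at 0.080, with epithelium at 0.0050 and the ciliated interaction at -0.018, where the direction of the test turned.

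The 1025 genes related to the bacteriology score were 2766 without the disease covariate, 0 in intercaruncular arrays (839), 644 with processed signals, 646 with the series matrix, 100 with scaling and 0 without the 2 highest scores (1509). In the intercaruncular fit the 3 doubted arrays carried the score of their labelled cows, 1 for each, while their closest cows had 7, 3 and 3. So this 0 does not show that the relation was absent in intercaruncular tissue. Leaving out single cows gave 0 (endometritis 3, 4, 6) to 1651 (endometritis 2), with 508, 679 and 166 without control 3, 5 and 6, and 46 and 251 without endometritis 1 and 5.

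Between 74.7% and 82.3% of probes per array were well above background, and the 12 cows limit what small differences can be seen. All planned settings were run. Quantile normalization of average signal leaves ratios as they were, so it tests nothing here.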

Other observations

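All tests of the bacteriology score in this part were chosen only after the results were seen. Across the caruncular arrays of 12 cows, neutrophil genes ran with the bacteriology score of the labels (0 to 9). S100A8 rose by 0.86 ± 0.12 on the log2 scale per point of the score, with the disease group in the model (limma adjusted p = 0.0202), S100A9 by 0.70 ± 0.10 and TGM3, a transglutaminase of epithelium, by 0.74 ± 0.10. The urokinase receptor PLAUR rose by 0.45 ± 0.06, the neutrophil attractants GRO1 by 0.62 ± 0.10, CXCL8 by 0.64 ± 0.11 and CXCL2 by 0.58 ± 0.10, the anaphylatoxin receptor C5AR1 by 0.14 ± 0.02 and the metal-binding MT2A by 0.41 ± 0.06. The Wnt inhibitor SFRP1 fell by 0.18 ± 0.03, the homeobox gene HOXD10 by 0.17 ± 0.02, the calcium channel gene CACNA1G by 0.25 ± 0.03 and the collagen gene COL6A1 by 0.17 ± 0.04. In all 1025 genes passed, 500 rising and 525 falling.

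Of 23 neutrophil markers 9 rose with the score (16 adjusted over the list alone, median 0.11 per point, camera adjusted p = 1.2e-11, fry adjusted p = 0.00635, and adjusted p = 0.319 with an estimated correlation). Cytokines rose for 9 of 36 (13 adjusted over the list alone), matrix proteases for 5 of 27 (8), complement genes for 5 of 26 (11) and antimicrobial genes for 4 of 24 (11). Of 22 stromal fibroblast markers 4 fell (5 adjusted over the list alone), but this list was not called (camera adjusted p = 0.0853). Camera also called macrophage (8 rose adjusted over the list alone, adjusted p = 3.64e-05) and B and plasma cell markers (6, adjusted p = 0.00055). So it did endothelial (6, adjusted p = 0.000551) and T and NK markers (0, adjusted p = 0.00395). With an estimated correlation these 4 lists were at adjusted p from 0.433 to 0.563. Antigen presentation (camera adjusted p = 0.000576), pattern recognition (0.00103), epithelium (0.00197), immediate early and heat shock (0.0372) and uterine gland genes (0.0445) were called as well. Their adjusted p was 0.403 to 0.563 with an estimated correlation. The score was related to the genes in caruncular, intercaruncular, averaged and differenced values, with and without the disease group, before this model was kept, and PMN percentages in caruncular endometritis arrays gave 0 genes.

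The neutrophil list mean of caruncular arrays correlated with the score at r = 0.897 (permutation p = 4e-04, adjusted p = 0.01 over 25 lists) and rho 0.639 (permutation p = 0.0286), and r was 0.67 without the 2 farthest cows. Within endometritis cows r was 0.935 (0.896 to 0.978 with single cows left out). Within control cows it was 0.663, and it turned to -0.407 without control 1, whose neutrophil mean of 0.01 lay far from the others, so the relation within controls rests on 1 cow. No test independent of this relation was run. For cytokines r was 0.795, and 0.28 without the 2 farthest cows. When the score was reassigned within the disease groups, 2 of 100 assignments gave as many genes as the 1025 found (highest other 1086), but the choice among the models was not repeated in them, so chance is not excluded by this. No gene was left without endometritis 3, 4 or 6 or without the 2 highest scores. Progesterone and slide were not separated from the score.

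Among intercaruncular arrays, those labelled control 2 and endometritis 4 correlated at r = 0.918 over 14820 bright probes, control 3 and endometritis 5 at 0.914 and control 4 and endometritis 6 at 0.902, and the next pair was at 0.791. The spread of the difference between the arrays of a pair, red over green channel, was 1.12, 1.66 and 1.89 in these pairs, against 1.51 at the lowest and a median of 2.81 in other pairs, so it does not set them apart, and whether they hold the same RNA was not shown.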
